A study of Mus musculus with 6 samples.

How the data were processed

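Total RNA of the mouse stromal cell line S17 was measured in 6 samples, 3 control and 3 treated with 100 ng/ml PDGF-BB for 72 h, on single-colour arrays of biotin-tagged cRNA, per the labels' protocols. The groups and replicate numbers were taken from the sample titles. The deposited table held log2 values, continuous and between 2.20 and 14.33 for the genes tested, judged to be log2 because on that scale they stay inside the range of a 16-bit scanner. The method by which the authors corrected background, normalized and summarised the probes is not given in the sources used here, and neither is a genome build, so no coordinates are printed. The columns shared nearly the same percentiles (medians 6.13 to 6.21), so the table was taken as normalized by the authors and used as deposited. Quantile normalization, which forces the columns onto a single distribution, was run as an alternative. A normalization that equalises arrays removes any change in total RNA per cell, and so the values are relative levels.

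The table had 16539 probe sets. The 64 control probe sets were left out of the tests, leaving 16475. Each probe set identifier is a gene number, with 1 probe set per gene, so the planned average over several probes of a gene was not needed. In the platform annotation used here, 15780 probe sets had exactly 1 gene symbol, 0 had several, and 695 had none and stayed unnamed. Of the named ones, 15752 had their gene number in the RefSeq gene table. No probe set with the symbol of erythropoietin was found among the named ones, and that gene is not analysed here. The arrays give no detection calls. The highest mean of a lymphocyte marker gene over all arrays, 5.24, was used as a gauge of dim signal, and 6358 probe sets (38.6%) had both group means at or below it, of which 682 passed the threshold.

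Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust, residual df 4, prior df 4.55), PDGF-BB against control, two-sided, over all 6 samples with no covariate. P-values were adjusted by Benjamini-Hochberg over all probe sets, with a threshold of 0.05. Values are log2 fold changes, PDGF-BB minus control, with the standard error from limma. The median standard error was 0.071, and the smallest change that was called was 0.15 (log2). The groups, tests, 24 gene lists, alternatives and the rule for named genes were fixed before the data were examined. That rule named the receptor genes Epor, Pdgfra and Pdgfrb, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, and for each list up to 2 members that rose and 2 that fell by the most, or the member with the smallest p where none was called. Unnamed and predicted transcripts were passed over when naming.

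Gene lists were tested with limma's camera at a preset correlation of 0.01, which compares members with all other genes, adjusted by Benjamini-Hochberg over the 24 lists. Camera with a correlation estimated from the data, which also tests on the 4 residual df alone, and fry were run beside it. With the preset correlation the df come from the number of genes instead. Calls within a list were also counted adjusted over the list alone. Some genes belong to more than 1 list, and list members without a named probe set were left out. The lists were HIF and hypoxia targets, glycolysis and lactate export, PDGF signalling, immediate early genes and MAPK feedback, mitosis, DNA replication, CDK inhibitors and p53 targets, collagens and matrix glycoproteins, smooth muscle and contractile genes, proteases and inhibitors, haematopoietic support factors, angiogenic factors, chemokines and NF-kB targets, interferon response, cholesterol synthesis, unfolded protein and amino acid response, TGF-beta and BMP targets, adipocyte and bone lineage genes, and markers of macrophages, erythroid, endothelial and epithelial cells and lymphocytes. In the closing section, medians of gene sets were set against those of 10000 random lists matched on mean level. Another 9 lists were written after the main results had been seen but before their own members' values were looked at.

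The alternatives were quantile normalization, subtraction of each array's median, restriction to probe sets above the 25th or 50th percentile of mean level, a trended and robust variance, a floor at the 10th percentile of all values (3.32), the replicate number as a block, each sample left out in turn, array weights, an unmoderated test, and thresholds of 0.01 and 0.1. Subtraction of the hybridization controls and limma's treat against a 1.5-fold change were added after the data had been seen.

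The steps were tested on simulated data for the 16475 probe sets, with the spread of these samples and 200 changed probe sets. With 3 samples per group limma recovered 36% of changes of 0.3 (log2), 100% of 0.5, 98% of 1 and 100% of 2, with 10 false calls. In the data 6094 probe sets passed, so the same adjusted p corresponds to a larger unadjusted p there. The 36% may therefore understate the recovery of small changes in the data. Camera called 0 lists when none was shifted and only mitosis when that list was shifted. The simulated genes were independent of each other, while the correlation estimated in the data was 0.46 for mitosis. The simulation therefore does not show how often camera wrongly calls lists of correlated genes. No 2 arrays held the same values: the SD of the differences between arrays of the same group was 0.14 to 0.18, and between groups it was 0.47 to 0.49.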

Results

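S17 is a mouse stromal cell line that supports blood cell precursors in culture. PDGF-BB, a dimer of platelet-derived growth factor B chains, is a mitogen of stromal and smooth muscle cells that binds PDGF receptors alpha and beta. Total RNA of 3 control samples and of 3 samples treated with 100 ng/ml PDGF-BB for 72 h was hybridised to single-colour arrays, with 1 array per sample. No dose or time was recorded here for the controls, so whether both groups spent the same time in culture is not established. The values analysed were log2 expression levels of 16475 probe sets, each standing for 1 gene, and 15780 of these had a gene symbol. Array medians lay between 6.18 and 6.21 in control samples and between 6.13 and 6.14 in PDGF-BB samples. Across genes, which are not independent replicates, arrays of the same group correlated at r = 0.997 to 0.998 and arrays of different groups at r = 0.980 to 0.982. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays, 3 in each group, limits the precision of every value.

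After PDGF-BB, 23 of 26 genes of the unfolded protein and amino acid response list rose (camera adjusted p = 1.72e-14; adjusted p = 0.0209 with an estimated correlation). All 25 mitosis genes, 24 of 28 DNA replication genes and 23 of 33 collagens and matrix glycoproteins fell. The camera calls of these 3 lists were lost when the correlation was estimated from the data (mitosis adjusted p = 0.139 with an estimated correlation; DNA replication adjusted p = 0.127 with an estimated correlation; collagens adjusted p = 0.0645 with an estimated correlation). That setting also tests on only the 4 residual df, so the loss need not come from correlated members. Among single genes, Smoc2, a secreted matrix protein that binds calcium, fell by a measured 46.1-fold (log2 fold change -5.53 ± 0.07, SE, n = 3 per group), and Adipoq, the fat cell hormone adiponectin, by 40.4-fold (-5.34 ± 0.12). The PDGF-BB means of both, 4.07 and 3.55, were at the level of dim signal, so neither the size of these falls nor their order is determined. Among the largest measured rises were those of Serpinb9g, a serine protease inhibitor, by 18.1-fold (4.18 ± 0.10), and of Crct1 (4.00 ± 0.10). Of the 16475 probe sets, 6094 passed an adjusted p of 0.05 in limma, 3275 higher and 2819 lower with PDGF-BB. At least 2-fold changes were found for 255 higher and 415 lower probe sets, and changes of at least 4-fold for 43 and 102. In 7941 probe sets (48.2%) all values of 1 group lay on the same side of all values of the other, where chance gives 10%. The share of calls that were higher was 53.7%, and it was 66.1% when each array's median was subtracted.

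Cth, which makes cysteine from cystathionine, rose by 12.2-fold (log2 fold change 3.60 ± 0.15, SE, n = 3 per group). Clec4d, a C-type lectin receptor, rose by 10.2-fold, the glutathione transferase gene Gsta2 by 8.48-fold, and the chemokine gene Ccl5 by 8.29-fold. Rcan2, a regulator of calcineurin, rose by 7.69-fold, and Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, by 7.61-fold. Among the falls, Hp, which encodes the haemoglobin-binding plasma protein haptoglobin, was 38.9-fold lower (-5.28 ± 0.09) and the carboxylesterase gene Ces1g 33.8-fold lower. The secreted Wnt inhibitor gene Wif1 was 30.9-fold lower, and the amine oxidase gene Aoc3 27.2-fold lower. Stc1, the hormone stanniocalcin 1, was also lower (-4.64 ± 0.06), and Id3, an inhibitor of helix-loop-helix transcription factors, was 23.4-fold lower (-4.55 ± 0.15). The adjusted p of these 16 genes ranged from 1.92e-09 for Smoc2 to 6.79e-07 for Gsta2. Serpinb9g, Gsta2 and Ces1g belong to families of closely related genes, and whether their probes also detect relatives was not tested. In 23 of the 89 genes named here, the dimmer group lay at or below 5.24, the highest mean of the lymphocyte marker genes. Their folds may be understated, and their order among the changes is not determined. They are Crct1, Cth, Rcan2, Smoc2, Adipoq, Ces1g, Wif1, Aoc3, Stc1, Slc7a11, Tnc, Myl9, Tnfrsf11b, Il34, Pdgfd, Mmp13, Plau, Msx2, Lyz2, Fcgr3, Vwf, Cldn7 and Cd3d. For Msx2, Fcgr3, Vwf, Cldn7 and Cd3d both group means lay at or below 5.24, so whether these genes were expressed at all is not established.

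**Figure D1:**
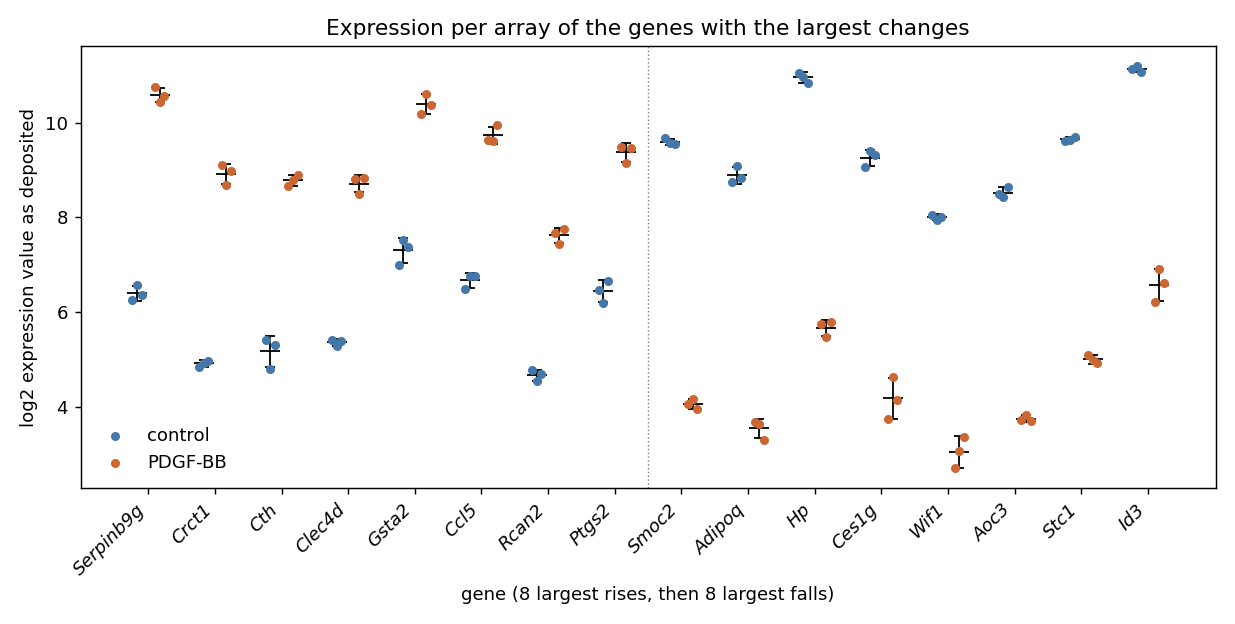
Log2 expression values (vertical axis, as deposited) of the 8 genes with the largest measured rises and the 8 with the largest measured falls (horizontal axis). Points are single arrays, 3 control in blue and 3 PDGF-BB in orange, and the black marks are group means with their SD. Control and PDGF-BB values do not overlap for any of the 16 genes, and Smoc2 went from a mean of 9.59 to 4.07.

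The gene for PDGF receptor beta, Pdgfrb, fell by 4.55-fold, from a mean of 10.78 ± 0.05 to 8.60 ± 0.14 (SD, n = 3 per group; log2 fold change -2.19 ± 0.08, SE; adjusted p = 1.67e-07). Pdgfra, the gene for receptor alpha, fell by 1.25-fold (-0.32 ± 0.07; adjusted p = 0.00604). The erythropoietin receptor gene Epor had a log2 fold change of 0.13 ± 0.08, with a 95% confidence interval of -0.04 to 0.31 (adjusted p = 0.227). The title of the series names erythropoietin, whose gene was not analysed here. Of 21 measured members of PDGF ligands, receptors and proximal signalling, 5 rose, 7 fell and 9 were not called, and 14 were called when adjusted over the list alone. Rasa1, a GTPase-activating protein of Ras, rose (1.03 ± 0.07), as did the ligand gene Pdgfc (1.02 ± 0.08), and the ligand gene Pdgfd fell (-1.07 ± 0.16). Camera did not call the list against other genes (adjusted p = 0.472), and fry did (adjusted p = 0.00106). Its median was 0.02, and its mean of -0.15 and the direction of the test were negative.

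All 25 measured mitosis genes fell, by a median log2 fold change of -0.85. Nusap1, a spindle protein, fell the most (-1.57 ± 0.12, SE, n = 3 per group), and Birc5, which encodes survivin, fell by 2.20-fold (-1.14 ± 0.12). Of 28 DNA replication genes, 24 fell, 1 rose and 3 were not called, with a median of -0.62. Tk1, the thymidine kinase of the salvage pathway, fell (-1.65 ± 0.12), and so did the origin licensing gene Cdc6 (-1.56 ± 0.12), whereas its partner in licensing, Cdt1, rose (0.62 ± 0.06). The same counts, 25 and 25, passed when adjusted over the list alone. The camera test with its preset correlation of 0.01 called both lists down (mitosis adjusted p = 3.91e-16; DNA replication adjusted p = 9.97e-12). Both calls were lost with an estimated correlation and 4 residual df (mitosis adjusted p = 0.139 with an estimated correlation; DNA replication adjusted p = 0.127 with an estimated correlation). Over the 53 genes of both lists, the median difference from the control mean was -0.88, -0.66 and -0.77 in PDGF-BB replicates 1, 2 and 3.

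Of 21 CDK inhibitors and p53 targets, 12 rose, 3 fell and 6 were not called, with a median of 0.40 and 16 called when adjusted over the list alone. The polo-like kinase gene Plk2 rose by 6.17-fold (2.63 ± 0.10, SE, n = 3 per group) and the DNA damage response gene Gadd45a by 3.64-fold (1.87 ± 0.06). Sesn1 fell (-1.21 ± 0.07), as did Cdkn2c, an inhibitor of CDK4 and CDK6 (-1.03 ± 0.06). Camera called the list up (adjusted p = 0.0104; adjusted p = 0.122 with an estimated correlation). Of 22 immediate early genes and MAPK feedback genes, 14 rose, 3 fell and 5 were not called, with a median of 0.35 and 20 called when adjusted over the list alone. The AP-1 subunit gene Fosl1 (1.75 ± 0.06) and the growth-promoting transcription factor gene Myc (1.68 ± 0.08) rose. Spry1, a feedback inhibitor of receptor tyrosine kinase signalling, fell (-1.81 ± 0.07), and so did Fos (-0.57 ± 0.08). The list was called up (adjusted p = 0.00283; adjusted p = 0.102 with an estimated correlation).

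The unfolded protein and amino acid response list had 26 measured members, of which 23 rose, none fell and 3 were not called, with a median log2 fold change of 1.20. The same number, 23, passed when adjusted over the list alone. Among them were Cth (3.60 ± 0.15, SE, n = 3 per group) and the cystine importer gene Slc7a11 (2.76 ± 0.10), whose control means of 5.18 and 4.74 lay in the range of dim signal, so that their folds may be understated. Camera called the list up (adjusted p = 1.72e-14), and the call held (adjusted p = 0.0209 with an estimated correlation), the only 1 of the 24 lists to do so. The list was split after the main results had been seen. The 18 members not on the ER chaperone side, here called amino acid response members, all rose, with a median of 1.45. The split does not show which stress raised them. Of the 8 members on the ER chaperone side 5 rose and none fell, with a median of 0.19. Of 20 glycolysis and lactate export genes 13 were measured, without Hk2, Gpi1, Gapdh, Pgk1, Pgam1, Eno1 and Ldha. Of the 13, 6 rose, 1 fell and 6 were not called, with a median of 0.31 and 9 called when adjusted over the list alone. The glucose transporter gene Slc2a1 (0.79 ± 0.07) and the lactate transporter gene Slc16a1 (0.75 ± 0.05) rose, and Pfkm, the muscle form of phosphofructokinase, fell (-0.27 ± 0.06). The list was called up (adjusted p = 0.0135; adjusted p = 0.373 with an estimated correlation). Of 27 HIF and hypoxia targets 22 were measured, without Pgk1, Ldha, Bnip3, Hk2 and Mif. Of the 22, 5 rose, 5 fell and 12 were not called, and 11 were called when adjusted over the list alone. Ndrg1 (1.16 ± 0.07) and the ER oxidase gene Ero1a (1.15 ± 0.07) rose, Lox (-2.99 ± 0.06) and Higd1a (-0.63 ± 0.06) fell, and the list was not called by camera (median -0.02; adjusted p = 0.895) but was by fry (adjusted p = 0.0195).

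Of 33 collagens and matrix glycoproteins, 23 fell, 2 rose and 8 were not called, with a median of -0.77, and 25 were called when adjusted over the list alone. Col6a1, a chain of collagen VI, fell by 8.17-fold (-3.03 ± 0.10, SE, n = 3 per group), and Lox, which cross-links collagen and elastin, by 7.97-fold. The matrix glycoprotein tenascin C, Tnc, rose by 6.27-fold (2.65 ± 0.06), and the microfibril gene Mfap5 by 1.41-fold (0.49 ± 0.10), a call lost in an unmoderated test (adjusted p = 0.0626). The list was called down (adjusted p = 9.97e-12; adjusted p = 0.0645 with an estimated correlation). Of 22 smooth muscle and contractile genes, 11 fell, 1 rose and 10 were not called, and 12 were called when adjusted over the list alone. Myl9, a regulatory light chain of myosin, fell by 21.6-fold (-4.43 ± 0.10), and smooth muscle actin, Acta2, by 14.3-fold (-3.84 ± 0.09). Pdlim7 rose by 1.16-fold (0.22 ± 0.07; adjusted p = 0.0446), and its adjusted p was 0.0711 with the replicate number as a block and 0.0692 when the hybridization controls were subtracted. Leaving out control replicate 2 or 3 or any PDGF-BB replicate also ended its call, with adjusted p from 0.0639 to 0.145, as did an unmoderated test (adjusted p = 0.112). The median of the list was -0.20 and its mean -1.03, and it was called down (adjusted p = 4.98e-07; adjusted p = 0.0645 with an estimated correlation).

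Of 19 TGF-beta and BMP targets, 11 fell, 3 rose and 5 were not called, with a median of -0.70 and 15 called when adjusted over the list alone. Id3 and Id1 (-3.54 ± 0.11, SE, n = 3 per group), immediate targets of BMP signalling, fell the most. The transcriptional repressor gene Tgif1 (1.43 ± 0.11) and Inhba, an activin subunit (0.96 ± 0.07), rose. The list was called down (adjusted p = 2.20e-05; adjusted p = 0.0645 with an estimated correlation). Of 23 proteases and inhibitors, 10 fell, 6 rose and 7 were not called, and 17 were called when adjusted over the list alone. The collagenase gene Mmp13 (1.56 ± 0.15) and the urokinase receptor gene Plaur (1.08 ± 0.09) rose, while urokinase itself, Plau (-1.31 ± 0.12), and the protease inhibitor gene Timp2 (-1.13 ± 0.05) fell. That list was not called by camera (median -0.12; adjusted p = 0.192) but was by fry (adjusted p = 0.0154).

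Of 25 haematopoietic support factors, 11 fell, 6 rose and 8 were not called, with a median of -0.16 and 17 called when adjusted over the list alone. Bmp4, a bone morphogenetic protein, fell by 18.7-fold (-4.22 ± 0.06, SE, n = 3 per group), and insulin-like growth factor 1, Igf1, by 14.4-fold (-3.85 ± 0.07). Il34, a ligand of the CSF1 receptor, rose by 2.64-fold (1.40 ± 0.13), and the lymphoid growth factor gene Il7 by 1.36-fold (0.45 ± 0.05). The list was called down (adjusted p = 0.00417; adjusted p = 0.122 with an estimated correlation). Of 30 angiogenic factors and inhibitors, 15 fell, 8 rose and 7 were not called, with a median of -0.20 and 23 called when adjusted over the list alone. Angpt4, an angiopoietin, fell by 5.62-fold (-2.49 ± 0.08), and Ccn2, also known as connective tissue growth factor, by 4.92-fold (-2.30 ± 0.07). Ptgs2 and Angptl4, an inhibitor of lipoprotein lipase (2.37 ± 0.06), rose. The list was called down (adjusted p = 0.0282; adjusted p = 0.417 with an estimated correlation). The adjusted p was 0.0896 and 0.0889 when only probe sets above the 25th or the 50th percentile of mean level were tested.

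Of 30 chemokines and NF-kB targets, 14 rose, 6 fell and 10 were not called, and 21 were called when adjusted over the list alone. Ccl5 (3.05 ± 0.11, SE, n = 3 per group) and Ptgs2 (2.93 ± 0.13) rose, and the chemokine gene Ccl9 (-2.38 ± 0.07) and Tnfaip3, an inhibitor of NF-kB signalling (-2.02 ± 0.08), fell. Camera did not call the list (median 0.18; adjusted p = 0.0735) and fry did (adjusted p = 0.00106). Camera called it up above the 50th percentile of level (adjusted p = 0.0207) and without control replicate 3, PDGF-BB replicate 2 or PDGF-BB replicate 3 (0.0492, 0.0403 and 0.0479). Of 26 interferon response genes, 14 rose, 6 fell and 6 were not called, and 22 were called when adjusted over the list alone. Rsad2, the antiviral enzyme viperin (2.40 ± 0.10), and Ifit2 (1.26 ± 0.09) rose, while the immunoproteasome subunit gene Psmb9 (-1.08 ± 0.09) and Ifi27l2a (-0.88 ± 0.06) fell. Camera did not call the list (median 0.26; adjusted p = 0.119) but called it up without control replicate 2 (adjusted p = 0.0451), and fry called it (adjusted p = 0.0201).

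Of 16 adipocyte lineage genes, 7 fell, 5 rose and 4 were not called, and 13 were called when adjusted over the list alone. Cebpa, a transcription factor of fat cell differentiation, fell (-2.06 ± 0.07, SE, n = 3 per group), as did Adipoq. The lipid droplet gene Plin2 (1.45 ± 0.06) and Cebpd (0.71 ± 0.07) rose. Camera did not call the list (median -0.16; adjusted p = 0.102) but called it down when each array's median was subtracted (adjusted p = 0.0412), and fry called it (adjusted p = 3.16e-05). Of 17 bone and cartilage lineage genes, 4 fell, 3 rose and 10 were not called, and 7 were called when adjusted over the list alone. Osteoprotegerin, Tnfrsf11b, which binds the osteoclast factor RANKL, fell by 17.2-fold (-4.11 ± 0.14), and osteomodulin, Omd, by 6.26-fold (-2.65 ± 0.06). Phex (1.83 ± 0.07) and Msx2 (0.72 ± 0.09) rose, although both group means of Msx2 were at the level of dim signal, as were those of 10 of the 17 genes. This list had a median of 0.01, a mean of -0.43 and a test direction that was down, and it was not called by camera (adjusted p = 0.378) but was by fry (adjusted p = 2.69e-05). Of 16 cholesterol synthesis genes, 5 fell, 3 rose and 8 were not called, and 8 were called when adjusted over the list alone. Msmo1 (0.34 ± 0.06) and Fdft1 (0.31 ± 0.06) rose, Dhcr7 (-0.73 ± 0.08) and Ebp (-0.48 ± 0.06) fell, and the list was not called by camera (median -0.11; adjusted p = 0.227) but was by fry (adjusted p = 0.0205).

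Marker lists of other cell types were not called by camera, and fry called only the erythroid list among them (adjusted p = 2.65e-04). Both group means were at the level of dim signal in 6 of 10 macrophage, 8 of 10 endothelial and 5 of 6 erythroid markers. The same held for 7 of 8 epithelial and 4 of 6 lymphocyte markers. The highest mean of these lymphocyte markers set the gauge, so their count says nothing by itself. Fcgr3, Vwf, Cldn7 and Cd3d were among these dim genes. Of 10 macrophage markers, 2 rose and 2 fell (adjusted p = 0.996), with Cd68 (0.68 ± 0.08, SE, n = 3 per group) and Cd14 (0.53 ± 0.10) higher and Lyz2 (-1.22 ± 0.11) and Fcgr3 (-0.45 ± 0.11) lower. The call of Fcgr3 was lost in an unmoderated test (adjusted p = 0.0803). Of 10 endothelial markers, Vwf rose (0.64 ± 0.09), Eng fell (-0.29 ± 0.06) and 8 were not called (adjusted p = 0.996). Of 6 erythroid markers, the transferrin receptor gene Tfrc rose (0.34 ± 0.06) and 5 were not called (adjusted p = 0.263). None of 8 epithelial markers was called (adjusted p = 0.996), and the smallest p was that of Cldn7 (0.09 ± 0.07; adjusted p = 0.355). Their median and mean were 0.01, and the direction of the test was down. None of 6 lymphocyte markers was called (adjusted p = 0.997), with Cd3d at 0.09 ± 0.10 (adjusted p = 0.552). When adjusted over the list alone, 4 macrophage, 2 endothelial, 1 erythroid, 0 epithelial and 0 lymphocyte markers were called in limma, and 0 epithelial and 0 lymphocyte markers had an unadjusted p under 0.05.

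**Figure D2:**
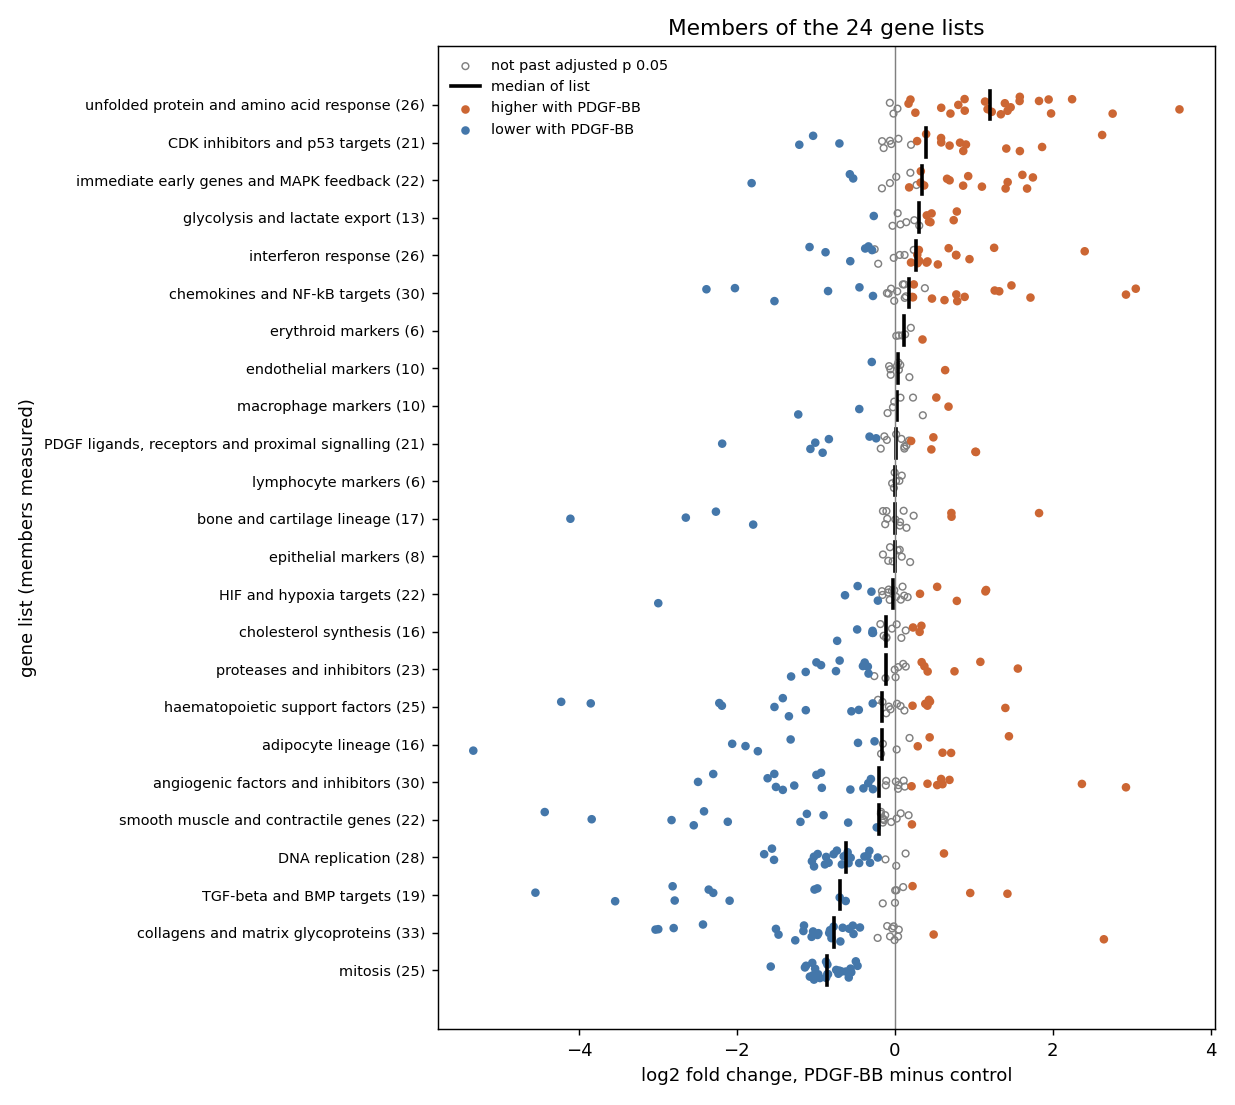
Log2 fold changes (horizontal axis, PDGF-BB minus control) of the members of the 24 gene lists (vertical axis, with the number measured), ordered by median. Filled points passed an adjusted p of 0.05 in limma (orange higher, blue lower), open points did not, and black bars are medians. All 25 mitosis genes lie below 0, and 23 of 26 unfolded protein and amino acid response genes are filled and above it.

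Camera called 11 of the 24 lists with its preset correlation, 4 up and 7 down, and 1 with an estimated correlation. The estimate was below the preset 0.01 for the smooth muscle (0.0086), TGF-beta and BMP (0.0081), immediate early (-0.0132) and CDK inhibitor (-0.0343) lists. A higher correlation among members therefore does not account for the loss of these calls. In the other lists that lost their call the estimate was between 0.0127 (haematopoietic support) and 0.46 (mitosis). With an estimated correlation camera also tests on only the 4 residual df. The loss of a call in any list therefore need not come from correlated members. Fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, called 20. The actin control probe sets, whose 3' minus 5' difference gauges RNA quality, differed by 0.53 ± 0.02 in control arrays (SD, n = 3) and by 0.93, 0.58 and 0.64 in PDGF-BB replicates 1, 2 and 3. Without PDGF-BB replicate 1, 5894 probe sets passed the threshold, and 5467 of them were among the 6094. In that fit 658 changed at least 2-fold and 11 lists were called.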

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

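The tests of RNA integrity on the Gapdh control probe sets and those against random lists matched on mean level were chosen only after the result was seen. Of 4 control genes with a 3' and a 5' probe set, 1 was higher in every PDGF-BB array than in every control array, actin, whose 3' minus 5' difference rose by 0.19 (log2, mean of 0.72 against 0.53). It lies outside the gene comparisons. PDGF-BB replicate 1 also had the lowest middle-region 18S rRNA signal, 10.46 against 11.31 to 11.74 in the other arrays. The 3' minus 5' difference of pyruvate carboxylase was lower with PDGF-BB, 1.78 against 2.68.

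For the actin difference, in replicate 1 the Gapdh difference exceeded the highest control by 0.19, where the controls span 0.05, as lower integrity there would give, so part of the pattern may be RNA quality. In replicates 2 and 3 the Gapdh difference lay -0.0236 and 0.02 from the highest control, and the actin excess over the highest control was 0.03 and 0.09. Lower integrity in these replicates stays open, since Gapdh there differed from the highest control by less than the controls span. Whether the actin probes also read other actins, such as Acta2, which fell by 14.3-fold, stays open and was not tested. No biological explanation was tested.

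Mitosis and DNA replication genes were lower with PDGF-BB, with 49 of 53 falling. A shift of the whole array, or a scaling that depends on signal level, is argued against. The 10000 random lists matched on mean level had a typical median of 0.03. The median of the members lay -0.77 from that and below all of them. Lying below all of them adds little, since these lists were flagged for their large fall. What the authors' own normalization did to single probe sets was not tested. Lower RNA integrity as the whole cause is argued against, as far as actin gauges it, since the median fall in replicates 2 and 3 was 0.814 times that in replicate 1, although the actin excess was far smaller there. A hypothesis is that fewer cells were in cycle after 72 h of PDGF-BB. The 38 further cell cycle genes had a median of -0.63, as it predicts (camera adjusted p = 0.0876 with an estimated correlation). They come from the same arrays and cannot tell fewer cells in cycle from lower levels of these RNAs per cell. Cell density, serum and growth arrest were not measured, and no time was recorded for the controls, so what lies behind such a difference stays open.

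Amino acid response genes rose more than ER chaperones. A shift of the whole array, or a scaling that depends on signal level, is argued against. The 10000 pairs of random lists matched on mean level had a typical difference of -0.02. The difference between both medians lay 1.28 above that and above all of them. Lying above all of them adds little, since the list was split after the results had been seen. The hypothesis put to a test was an amino acid (ATF4) response that leaves most ER chaperones out. In genes outside the list, 29 further ATF4 targets had a median 0.74 above that of 26 further ER chaperones (two-sided permutation test over genes, which are not independent replicates, p = 1e-05, the smallest 100000 permutations can give). However, 11 of those 26 chaperones rose, as did 5 of the 8 in the list, against 3275 of all 16475 probe sets. These values show a smaller rise of the chaperones, and not that most were left out. Whether amino acid supply in the medium differed between the groups was not measured and stays open.

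There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 6094 calls, 3275 higher, 2819 lower and 670 changed at least 2-fold, and the highest of the other splits gave 0 of each in limma, with 197 to 348 probe sets at an unadjusted p under 0.05 against 7383. For each of these counts 1 split, the real one, gave as many. For gene lists the real split gave 11 and the highest of the others 6, and all 9 others gave 3 to 6 lists although they called 0 probe sets, so a list call with the preset correlation needs no called probe set. Each of those splits still sets 2 arrays of a group against 1, and mixes control and PDGF-BB arrays on both sides. That mixing widens the spread within a side, so 0 calls were close to fixed in advance and say little about chance.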

How the results depend on the processing

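The tests with hybridization controls subtracted and against a 1.5-fold change were chosen only after the result was seen. The count of calls was 6094, and between 4358 (adjusted p under 0.01) and 7164 (under 0.1) in every planned setting. Tested against a 1.5-fold change, 891 passed, 338 higher and 553 lower, since small changes no longer count. Camera with an estimated correlation called 1 list and fry 20, in place of 11. Leaving out each sample in turn gave 5260 to 5894 calls, 2751 to 3152 higher, 2483 to 2742 lower, 654 to 705 changed at least 2-fold and 11 to 12 lists. The replicate numbers do not pair the samples (correlations of deviations of -0.03, 0.01 and -0.01), and with the replicate block 5796 probe sets passed, 3085 higher and 2711 lower, with 670 at least 2-fold and 11 lists. Of the 89 named genes, 0 reversed. Against a 1.5-fold change 23 lost their call, in an unmoderated test 3 (Pdlim7, Mfap5 and Fcgr3), and Pdlim7 alone in the other settings. No list reversed. Fry called 9 lists that camera did not, and the lists of angiogenic, chemokine, interferon and adipocyte genes changed their camera call under a scaling, a filter or a sample left out. The 50th percentile filter left 20 named genes untested and 5 lists with too few members, and the 25th left 2 genes untested. The mean over several probes of a gene was not run, since each gene had 1 probe set. What limits dim genes is signal over background, since arrays give no detection calls here.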

Other observations

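The tests on the 9 lists below were chosen only after the main result was seen, before their members' values were looked at, and the genes named are among the largest measured changes, chosen after their values were seen. Of 29 further ATF4 and amino acid response targets, 26 rose and 0 fell, with a median log2 fold change of 0.89 (camera adjusted p = 1.80e-14; adjusted p = 0.00795 with an estimated correlation). The alanine aminotransferase gene Gpt2 rose by 1.37 and the translation inhibitor gene Eif4ebp1 by 1.34, on the log2 scale. Of 26 further ER chaperones and folding enzymes, 11 rose, 3 fell and 12 were not called (adjusted p = 0.0789), with Serp1 at 0.63 and Txndc5 at -0.26. Of 26 NRF2 targets, 17 rose and 5 fell, with a median of 0.53 (adjusted p = 8.90e-04; adjusted p = 0.0876 with an estimated correlation). Haem oxygenase 1, Hmox1, rose by 1.53 and the aldehyde oxidase gene Aox1 fell by 1.36. Of 38 further cell cycle genes, 34 fell and 1, Dut, rose, with a median of -0.63 (adjusted p = 1.83e-15; adjusted p = 0.0876 with an estimated correlation).

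Of 25 YAP and actin-SRF targets, 15 fell and 4 rose, with a median of -0.28 (adjusted p = 9.10e-05; adjusted p = 0.0876 with an estimated correlation), led by Amotl2, which fell by 1.68, and Fhl2, which fell by 1.59. Of 24 complement and coagulation genes, 9 fell and 2 rose, with a median of -0.13 (adjusted p = 0.0107; adjusted p = 0.0876 with an estimated correlation). The complement protease gene C1ra fell by 1.91 and tissue factor, F3, fell by 1.48. Of 31 Wnt ligands, antagonists and targets, 9 fell, 2 rose and 20 were not called (adjusted p = 0.0373; adjusted p = 0.0942 with an estimated correlation), with Ccn5 at -2.10. Of 33 growth factor receptors, 10 fell and 2 rose (adjusted p = 0.0789), with Tgfbr3 at -0.86 and Epha2 at 1.07. Of 28 lysosome and autophagy genes, 7 rose and 5 fell (adjusted p = 0.865), with a median of -0.01, a mean of 0.04 and a test direction that was down.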
